A study of Rattus norvegicus with 6 samples.

How the data were processed

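Small RNA was sequenced, single-end, from exosomes that had been isolated with an isolation reagent from the culture supernatant of rat mesenchymal stem cells (MSCs). There were 3 libraries from untreated MSCs and 3 from MSCs pretreated with 200 µM nicorandil for 24 h. Per the submitters' processing notes, FastQC, Bowtie and edgeR were used. Their versions, the genome build and the miRNA annotation are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate cultures. The p-values of single miRNAs between the groups therefore measure the spread between these samples, which may be technical. Permutation p-values for the markers as a set and for neighbouring genes rest on the spread between miRNAs, with the 6 libraries fixed, and show no replication.

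The deposited table lists 763 mature miRNAs with 1 value per library, and the unit of these values was established from the values themselves. They are a normalized read-count signal that the authors deposited, neither scaled to a fixed library total nor raw counts. The deposited values have the form of edgeR pseudo-counts: the reads of each library are mapped by a quantile adjustment to 1 common library size, with a negative binomial dispersion of 0.0272. Inverting that formula gave whole reads for 100% of the 763 miRNAs, with a relative tolerance of 1e-05 and a largest mismatch of 2.5e-09. Recomputing the pseudo-counts from those reads gave the deposited values to within 4.8e-07. A miRNA with no read in a group is listed by the authors at a placeholder near 0. The authors' deposited table also holds a log2 fold change and an unadjusted p-value per miRNA, per the file headers. Both followed from the recovered reads with edgeR's exact test, to within 5.0e-10 on the log2 scale and 8.6e-04 on the log10 p scale, among p-values under 0.05.

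The depth was low and differed between the groups. The untreated libraries held 2224, 2212 and 2338 miRNA reads and the nicorandil libraries 16628, 16324 and 8426. In the deposited signal 1 read was worth 1.93, 2.17 and 2.09 units in the untreated libraries and 0.375, 0.396 and 0.771 units in the nicorandil libraries. A count of 0 reads allows up to 3 reads, which is a share of up to 0.135%, 0.136% and 0.128% of an untreated library and 0.018%, 0.0184% and 0.0356% of a nicorandil library. PCR reads without molecular identifiers are not independent molecules, so these limits and the Wilson and conditional exact intervals cover counting error only. The simulated interval of the marker reads also rests on the dispersion in the deposited values. The bootstrap intervals in the closing section describe the spread between the picked miRNAs and not the counting error of their reads. The total number of reads sequenced per library is not given in the sources used here.

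Before the data were examined, the design, the named miRNAs, 19 miRNA lists and most alternatives were fixed for a table of raw counts or of RPM, CPM or TPM values. The test planned for raw counts was edgeR's quasi-likelihood test after filterByExpr, and the test planned for normalized values was limma. Since the table held pseudo-counts, the test planned for normalized values was used. limma with an intensity trend (limma 3.58.1, R 4.3.3) was run on log2(value + 1) for the 121 miRNAs with a mean value of at least 1 over the 6 libraries, without covariates. A fold change is therefore on the log2(value + 1) scale, which understates the change of miRNAs with few reads. The threshold was a Benjamini-Hochberg adjusted p of 0.05, with no minimum fold. Means ± SD are of the deposited values, with n = 3 per group. The fold against a group with 0 reads was computed against a floor of 3 reads over the group, on the TMM scale. The counting error of the reads in the other group was left out.

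The rule for the miRNAs named took up to 10 rises and up to 10 falls, the largest among those past the threshold whose groups did not overlap (10 rises and, since no more passed, 9 falls), the 10 most abundant, miR-125a-5p, and up to 4 abundant members of each list. miR-125a-5p was included because a paper on these exosomes is recalled to follow it up, so its result is not independent evidence. Others named are said to have been chosen after their values were seen. Lists with at least 3 tested members, 13 of the 19, were tested with camera at a preset inter-gene correlation of 0.01. fry and camera with an estimated correlation were run beside it, and p-values were adjusted over the 13 lists. Shares of all miRNA reads were compared with a two-sided exact permutation test, for which 0.1 is the smallest p that 3 against 3 libraries allow.

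Alternatives were other scalings of the recovered reads (median of ratios, library totals, upper quartile), other filters, pseudocounts of 0.1 and 10, DESeq2 1.42.0, the exact test of edgeR 4.0.16, limma-voom, the replicate number as a block, and each library left out in turn. edgeR's quasi-likelihood test, planned for raw counts, was run on the recovered reads as an alternative after the data were seen. Other alternatives chosen after seeing the data were the authors' deposited p-values adjusted over all 763 miRNAs, recovered reads divided by TMM sizes, and untreated replicates 1 and 2 averaged as 1 sample. All libraries were also thinned to 2212 reads in 100 draws, with TMM sizes recomputed in each draw, a choice likewise made after seeing the data. For the closing section a miRNA counted as past the threshold at equal depth if it passed in at least 95% of the draws. This cut replaced one of 50%, which 5 lower and 3 higher miRNAs met, after the results under 50% had been seen. The average of 2 replicates was added because the reads of untreated replicates 1 and 2 differed by no more than sampling noise (chi-square over 54 miRNAs, permutation p = 0.735). They were kept as 2 samples, since their reads were not identical and untreated replicates 1 and 3 did not differ beyond sampling noise either (permutation p = 0.143), whereas replicates 2 and 3 did (permutation p = 0.0143). At full depth every pair of nicorandil libraries differed beyond sampling noise (chi-square, permutation p = 0.0001 for each pair). Thinned to the same depth as the untreated libraries, nicorandil replicates 1 and 2 gave a p above 0.05 in 68 of 100 draws. Each of them against replicate 3 did so in 0 of 100. Agreement at the untreated depth can therefore hide a difference and does not show that 2 libraries are 1 sample, so the question is not settled.

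The test was also run on simulated data with the depths, means and dispersion of this comparison, about 125 tested miRNAs and 24 changed ones. limma called 35.7% of changes of 2-fold and 61.3% of changes of 4-fold, and 15.2% of its calls were false, against 7.65% for edgeR's quasi-likelihood test. In 50 simulated data sets without changes, limma made 0.6 calls on average and 5 at most. Limits for the statistics on marker reads in the closing section came from 999 data sets (equality of reads: 9999) simulated with the dispersion of 0.0272. The test on the reads of each marker was added after that on their sum had been seen, as were the tests of the marker set with neighbouring genes merged and with camera after that on single miRNAs. Neighbouring miRNA genes were looked up in the RefSeq annotation of assembly GRCr8, which matched 120 of the 121 tested miRNAs by name; no coordinates are given because the build behind the table is not known. Python 3.11.15, numpy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.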

Results

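The miRNA content of exosomes, small vesicles that cells release, was compared between rat MSCs pretreated with nicorandil and untreated MSCs. Nicorandil is an anti-anginal drug that opens ATP-sensitive potassium channels and donates nitric oxide. The comparison asked which exosomal miRNAs differ after the pretreatment. Of the 763 miRNAs listed, 250 had a read in any of the 6 libraries. The 3 untreated libraries held 6774 miRNA reads together and the 3 nicorandil libraries 41378, so depth differed 6.11-fold in the same direction as the treatment. In the untreated libraries 110, 103 and 118 miRNAs had a read, against 192, 171 and 166 in the nicorandil libraries.

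Few miRNAs made up most of both kinds of exosome library. miR-143-3p, a miRNA of mesenchymal and smooth muscle cells, was the most abundant at 1050 ± 84.1 normalized reads in untreated and 1541 ± 160 in nicorandil exosomes (SD, n = 3). It was followed by miR-148a-3p, miR-423-5p, miR-24-3p and miR-328a-3p. The 10 most abundant miRNAs took 63.4% ± 1.0 of all miRNA reads in untreated and 69.0% ± 0.13 in nicorandil exosomes (SD, n = 3). The groups did not overlap, but the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, and 0.182 after adjustment over the 20 shares compared. Of these 10 miRNAs, 5 rose with nicorandil, namely miR-143-3p, miR-148a-3p, miR-320-3p, miR-21-5p and miR-99a-5p. With library totals as the scale 3 of them were not called: miR-143-3p at 0.09, miR-21-5p at 0.17 and miR-99a-5p at 0.42 (limma adjusted p = 0.615, 0.528 and 0.0636). The share of miR-143-3p overlapped between the groups, at 22.2%, 23.1% and 22.3% of untreated and 25.7%, 25.7% and 20.9% of nicorandil libraries. The other 5 did not pass the threshold in limma. Among them miR-423-5p had a log2 fold change of 0.34, miR-128-3p 0.34, miR-191a-5p 0.25, miR-24-3p 0.03 and miR-328a-3p -0.16. Under library totals miR-423-5p, miR-128-3p and miR-191a-5p lay at -0.12, -0.12 and -0.20, and miR-24-3p and miR-328a-3p were lower at -0.43 and -0.62 (limma adjusted p = 0.02 and 0.0191).

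After nicorandil 17 miRNAs were higher and 9 lower among the 121 tested (limma, Benjamini-Hochberg adjusted p under 0.05). In the simulated data 15.2% of limma's calls were false, above the rate of 0.05 that the threshold names, so some of these calls may be false. The test planned for raw counts, edgeR's quasi-likelihood test with filterByExpr, gave 7 higher and 6 lower among the 55 miRNAs it kept. The strongest evidence for a rise was for miR-148a-3p, which went from 462 ± 45.0 to 996 ± 46.3 normalized reads (log2 fold change 1.11, SE 0.11, limma adjusted p = 2.7e-06). miR-320-3p went from 100.4 ± 7.66 to 266 ± 131, a log2 fold change of 1.30 (SE 0.23). Nicorandil replicate 3 accounted for that spread: miR-320-3p took 6.38% of its reads (95% Wilson interval 5.88% to 6.93%), against 3.09% and 3.01% in the other nicorandil libraries and 2.11% to 2.18% in untreated ones. miR-99a-5p rose from 86.5 ± 2.26 to 160 ± 5.66 and miR-99b-5p from 34.4 ± 0.57 to 67.8 ± 10.9. miR-21-5p, an abundant miRNA linked to cell survival and fibrosis, rose from 112 ± 21.8 to 171 ± 5.52. miR-30d-5p rose by 0.79 on the log2 scale, miR-100-5p by 1.02 and miR-23a-3p by 1.11. Both miR-145-5p, a smooth muscle and mesenchymal miRNA made from the same cluster as miR-143-3p, and miR-93-5p had no read in any untreated library. With 46 and 24 reads over the nicorandil libraries, they were at 3.45-fold and 1.80-fold a floor of 3 reads over the untreated group. These folds hold on the TMM scale and leave out the counting error of the nicorandil reads, so they are not lower limits. Of the 17 other settings on unthinned reads, 15 called miR-145-5p and 2 called miR-93-5p, whose adjusted p was 0.0565 with library totals (limma) and 0.0911 in the quasi-likelihood test of edgeR. The remaining higher miRNAs, named after their values were seen where no list holds them, were miR-674-3p, miR-10b-5p, miR-151-3p, miR-146b-5p and miR-27a-3p, with log2 fold changes of 0.63 to 1.28.

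miR-10a-5p, a miRNA encoded within a HOX gene cluster, had the most negative fitted change and fell from 37.8 ± 14.4 to 3.07 ± 1.28 normalized reads (log2 fold change -3.24, SE 0.39, limma adjusted p = 1.7e-05). It had 55 reads in the shallow untreated libraries and 20 in the deeper nicorandil libraries. Most other lower miRNAs are known as markers of cell types other than MSCs. miR-122-5p, which is specific to hepatocytes, fell from 69.8 ± 24.3 to 23.5 ± 5.61, and miR-126a-3p, an endothelial miRNA, from 13.0 ± 2.77 to 1.99 ± 0.31. The epithelial miR-200b-3p fell from 7.55 ± 2.04 to 0.60 ± 0.34, which rests on 11 and 4 reads. miR-194-5p and miR-192-5p, enriched in liver and gut, fell by 2.30 and 1.11 on the log2 scale, and miR-486, abundant in red blood cells, by 1.20. miR-194-5p rests on 9 untreated and 4 nicorandil reads, the latter all in nicorandil replicate 1. It did not pass in edgeR's quasi-likelihood test (adjusted p = 0.062). let-7f-5p fell from 61.0 ± 6.36 to 29.6 ± 13.3 and miR-30c-5p from 15.2 ± 4.16 to 4.65 ± 2.45.

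**Figure D1:**
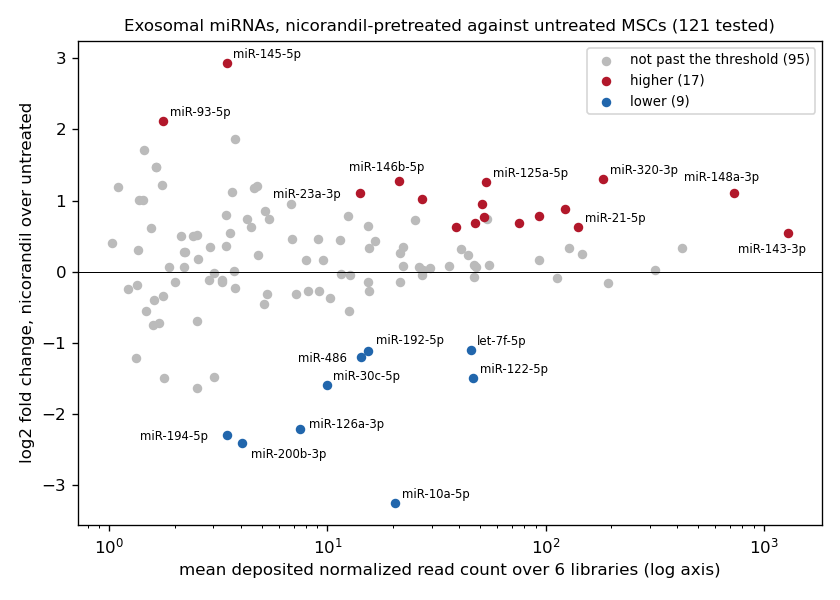
Log2 fold change of nicorandil over untreated exosomes (vertical axis) against the mean deposited normalized read count over the 6 libraries (horizontal log axis) for the 121 tested miRNAs, 1 point each. The 17 higher miRNAs (red) reach up to the most abundant, miR-143-3p at 0.55, while the 9 lower ones (blue) lie between -1.10 and -3.24; fitted values of miR-145-5p and miR-93-5p, with 0 untreated reads, are not fold estimates.

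The values of the groups did not overlap for 16 of the 17 higher miRNAs, with miR-146b-5p the exception, and for all 9 lower ones. Among all tested miRNAs 34 were separated in this way (28.1%, where chance gives 10% for libraries of like depth and scale). Depth differed between the groups and the median log2 fold change of all tested miRNAs was 0.23, so the excess over 10% is no evidence of an effect. miR-1843b-5p, picked after its values were seen, was separated with 0 untreated and 11 nicorandil reads, at 0.82-fold the floor on the TMM scale. The number of rises depended on the scale: 6 higher and 9 lower with median-of-ratios scaling, 4 and 11 with library totals (miR-148a-3p, miR-125a-5p, miR-320-3p and miR-145-5p higher), which move the median of all tested miRNAs by -0.35 on the log2 scale, and 6 and 7 with upper-quartile scaling. Without nicorandil replicate 2 there were 6 higher and 5 lower miRNAs, without untreated replicate 2 there were 13 and 5, and at an equal depth of 2212 reads a median of 3 and 5. miR-27a-3p lost its call whichever library was left out. Of the 6 fits without a library, miR-23a-3p, miR-151-3p, miR-146b-5p and miR-192-5p kept their calls in 1, miR-93-5p, miR-486 and miR-194-5p in 2, miR-21-5p, miR-100-5p and miR-30c-5p in 3, miR-10b-5p, miR-674-3p and let-7f-5p in 4, and miR-143-3p and miR-30d-5p in 5. Among the 17 other settings on unthinned reads, the fewest kept the calls of miR-93-5p (2), miR-27a-3p (4), miR-146b-5p (6) and miR-23a-3p (7).

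**Figure D2:**
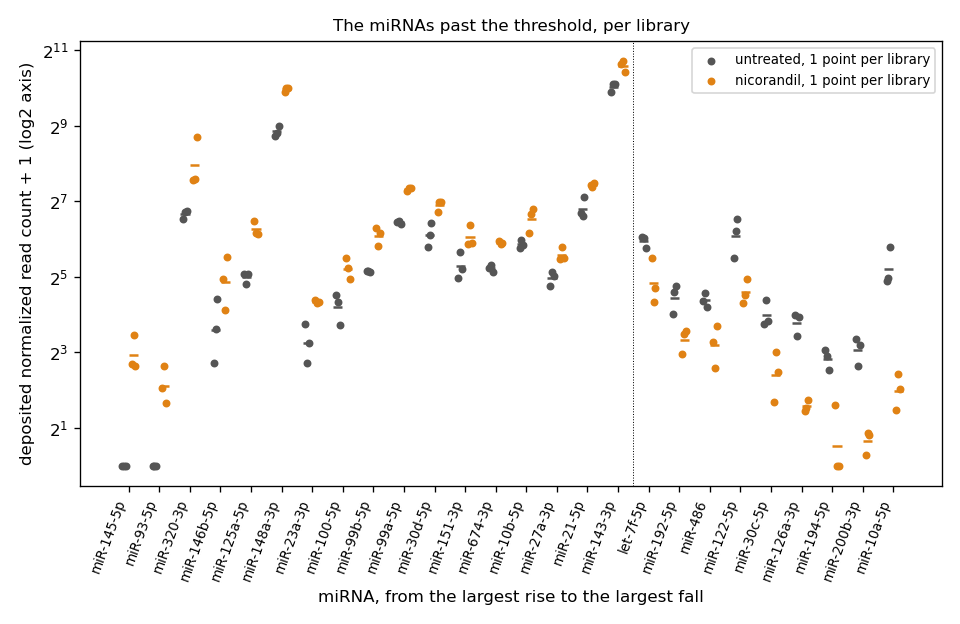
Deposited normalized read count plus 1 (vertical log2 axis) of the 26 miRNAs past the threshold, 1 point per library, with untreated libraries in grey and nicorandil libraries in orange; bars are group means on the log scale. miRNAs are ordered by fitted log2 fold change, with the 17 higher ones left of the dotted line and the 9 lower ones right of it.

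miR-125a-5p, which the study is recalled to have followed up, rose from 30.9 ± 3.26 to 75.8 ± 10.1 normalized reads (log2 fold change 1.27, SE 0.20, limma adjusted p = 0.000309). Its share of all miRNA reads was 0.764%, 0.542% and 0.684% in the untreated libraries, from 45 reads together. In the nicorandil libraries it was 1.38%, 1.10% and 1.07%, from 500 reads. The lowest nicorandil share had a 95% Wilson interval of 0.87% to 1.31% and the highest untreated share 0.478% to 1.22%. The authors' deposited table gives a log2 fold change of 1.30 for it. At equal depth its log2 fold change had a median of 0.94 with a limma adjusted p of 0.0503, short of the threshold.

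The miR-125 and miR-99/100 families, related miRNAs that are partly encoded in shared clusters, rose as a list (camera, adjusted p = 0.0328; adjusted p = 0.208 with an estimated correlation). Of its 8 tested members 5 rose, miR-10a-5p fell and 2 did not pass, with a median log2 fold change of 0.91; adjusted over the list alone, 7 rose and 1 fell. The risers were miR-125a-5p, miR-99a-5p, miR-99b-5p, miR-100-5p and miR-10b-5p, the last from 57.1 ± 4.56 to 93.6 ± 21.1. miR-10b-5p differs from miR-10a-5p by a small sequence change, so reads of this pair could be split between them in counting. miR-125b-5p had 38.3 ± 9.39 and 69.3 ± 34.2 normalized reads and did not pass. The list holds miR-125a-5p, recalled as the miRNA the study followed up, and miR-99b-5p, whose gene is its neighbour. Its rise is therefore not independent evidence for miR-125a-5p. The mesenchymal-enriched list also rose (camera, adjusted p = 0.0328; adjusted p = 0.208 with an estimated correlation), with 4 of 11 tested members higher, none lower and 7 not past, and a median of 0.63. The same 4 rose adjusted over the list alone: miR-143-3p, miR-145-5p, miR-21-5p and miR-100-5p, while miR-22-3p was at 46.7 ± 1.19 and 49.2 ± 5.25. As a share of all miRNA reads it was 28.0% ± 0.44 in untreated and 29.9% ± 2.92 in nicorandil exosomes (SD, n = 3), within the spread of the libraries (two-sided exact permutation p = 0.4), while the liver and gut markers were lower in the same nicorandil libraries. Under library totals the median log2 fold changes of both lists were 0.46 and 0.33 and neither list passed. Each also lost its call without untreated replicate 1 or 3 and without nicorandil replicate 1 or 2, with adjusted p-values of 0.0574 to 0.0903.

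Markers of liver and gut fell as a list (camera, adjusted p = 0.00264; adjusted p = 0.208 with an estimated correlation). All 3 tested members were lower, miR-122-5p, miR-192-5p and miR-194-5p, with a median log2 fold change of -1.49, and all 3 also adjusted over the list alone. The genes of miR-192-5p and miR-194-5p are neighbours, so these members may not be independent. Together this list took 2.07% ± 0.59 of the miRNA reads in untreated and 0.526% ± 0.081 in nicorandil exosomes (SD, n = 3). Endothelial markers took 0.28% ± 0.091 and 0.0321% ± 0.003, epithelial markers 0.309% ± 0.080 and 0.0302% ± 0.0062, and blood cell markers 0.753% ± 0.091 and 0.339% ± 0.076. Each of these 4 shares was lower in all 3 nicorandil libraries, with a two-sided exact permutation p of 0.1, the smallest possible (0.182 adjusted). The blood cell list did not pass (camera, adjusted p = 0.395), with miR-486 lower, also adjusted over the list alone, and miR-451-5p and miR-142-5p not past, at log2 fold changes of -0.27 and 0.36. The endothelial list had 1 tested member, miR-126a-3p, which fell. The epithelial list had 2, of which miR-200b-3p fell and miR-200a-3p, at -1.49, did not pass. The neuronal list had 2, miR-128-3p at 0.34 and miR-129-5p at -0.74, and neither passed. No muscle marker had enough reads to be tested; miR-133a-3p and miR-499-5p had reads only in nicorandil libraries, at 0.0061% of the reads on average.

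**Figure D3:**
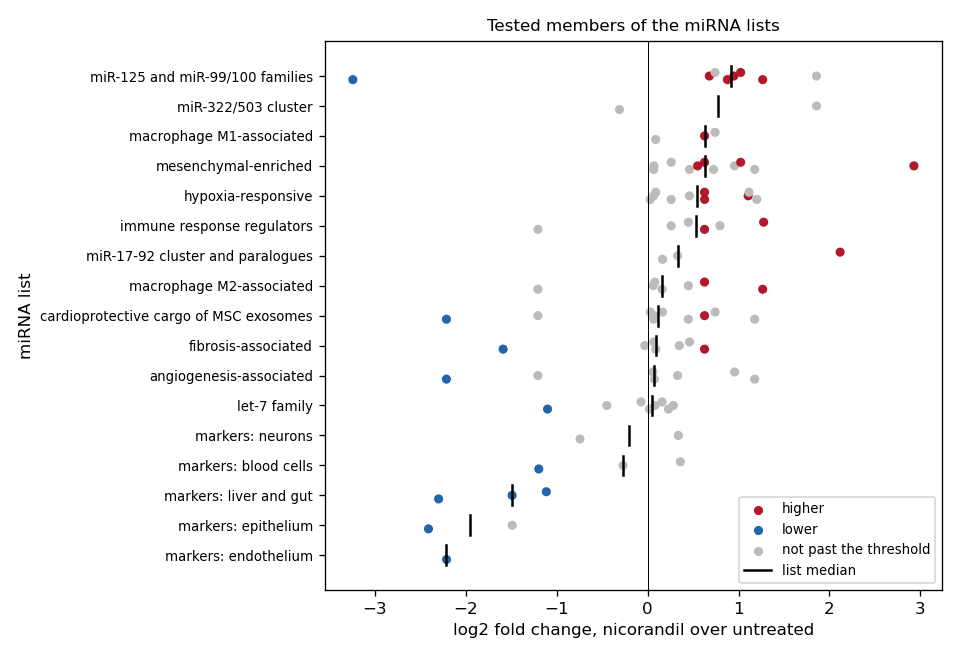
Log2 fold change of nicorandil over untreated exosomes (horizontal axis) for the tested members of each miRNA list (vertical axis), 1 point per miRNA, red for higher, blue for lower and grey for not past the threshold; black bars are list medians. The miR-125 and miR-99/100 families have a median of 0.91 and the liver and gut markers one of -1.49.

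The other lists with at least 3 tested members did not pass in camera, which compares a list with the other miRNAs. fry, which tests only whether the members lie on balance above or below 0, passed for 3 of them, all upward: the hypoxia-responsive list (adjusted p = 0.00179), the list associated with M1 macrophages (0.0152) and the list of the miR-17-92 cluster with its paralogues (0.0152). The last had 3 tested members, miR-92a-3p and, from the paralogous miR-106b-25 cluster, miR-93-5p and miR-25-3p, while miR-17-5p, miR-18a-5p, miR-19a-3p and miR-19b-3p had no read, so this is no result for the miR-17-92 cluster itself. The medians of these 3 lists were 0.54, 0.63 and 0.33 on the log2 scale, and 0.18, 0.18 and -0.07 with library totals. fry also passed for the 3 lists that passed in camera, with adjusted p-values of 0.00119 to 0.00313, and for none of the other 7. The let-7 family had 1 of 8 lower, let-7f-5p, also adjusted over the list alone, with a list adjusted p of 0.474; let-7c-5p and let-7i-5p were at log2 fold changes of 0.16 and -0.07. For the list associated with M2, or alternatively activated, macrophages, 2 of 7 rose, miR-125a-5p and miR-21-5p, as they did adjusted over the list alone (list adjusted p = 0.521). This list holds miR-125a-5p, which the study is recalled to have followed up, so it is not independent evidence. For the list associated with M1, or inflammatory, macrophages, 1 of 3 rose, miR-27a-3p, whose call any left-out library ended, and 2 rose adjusted over the list alone (list adjusted p = 0.474). Of 6 regulators of immune responses 2 rose, miR-21-5p and miR-146b-5p, also adjusted over the list alone (list adjusted p = 0.521), while miR-146a-5p was at 0.45. Of 10 hypoxia-responsive miRNAs 3 rose, miR-21-5p, miR-23a-3p and miR-27a-3p, also adjusted over the list alone (list adjusted p = 0.39). None of these 3 was called with library totals, and the list as a whole took 12.3% ± 1.0 of the reads in untreated and 10.7% ± 0.20 in nicorandil exosomes (SD, n = 3). In the angiogenesis-associated list 1 of 7 fell, miR-126a-3p, also adjusted over the list alone (list adjusted p = 0.521). The cardioprotective cargo of MSC exosomes had miR-21-5p higher and miR-126a-3p lower among 10, also adjusted over the list alone (list adjusted p = 0.84). In the fibrosis-associated list miR-21-5p was higher and miR-30c-5p lower among 7, also adjusted over the list alone (list adjusted p = 0.84). For the miR-17-92 cluster and its paralogues, 1 of 3 rose, miR-93-5p, also adjusted over the list alone (list adjusted p = 0.521), and miR-92a-3p and miR-25-3p were at 0.33 and 0.16. The cluster of miR-322 and its neighbours had 2 tested members, neither past the threshold, with miR-351-5p passing adjusted over the list alone. No member of the Dlk1-Dio3 imprinted cluster reached a mean of 1 normalized read, and 7 of its 38 members had a read at all. Its share of the reads was 0%, 0.0452% and 0% in the untreated and 0.0601%, 0.0735% and 0.0831% in the nicorandil libraries, and a count of 0 allows up to 0.135% and 0.128% in those untreated libraries. Other shares that did not overlap between the groups were those of the let-7 family (6.63% ± 0.55 and 4.59% ± 0.41), the angiogenesis-associated list (1.85% ± 0.28 and 1.42% ± 0.22), the miR-125 and miR-99/100 families (6.54% ± 0.45 and 8.0% ± 0.39) and the cluster of miR-322 (0.147% ± 0.049 and 0.201% ± 0.022), in untreated and nicorandil exosomes (SD, n = 3). For each of these 4, the hypoxia-responsive list and the Dlk1-Dio3 cluster the two-sided exact permutation p was 0.1, the smallest possible, and 0.182 after adjustment.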

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

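edgeR's quasi-likelihood test was the one planned for raw counts, but its use on the recovered reads was chosen after the data were seen. So were the authors' p-values, TMM-scaled reads, thinning and averaged untreated replicates 1 and 2. Against 17 higher and 9 lower miRNAs (26 in all, limma), the split was 6 and 9 (15) with median-of-ratios scaling, 4 and 11 (15) with library totals, and 6 and 7 (13) with upper-quartile scaling. It was 5 and 9 (14) with DESeq2, where 9 adjusted p-values were not given, 9 and 10 with limma-voom, and 14 and 9 with edgeR's exact test. The quasi-likelihood test gave 13 and 8 on the same miRNAs and 7 and 6 (13) on the 55 that filterByExpr kept. The authors' deposited p-values, adjusted over all 763, gave 8 and 4 (12), and TMM-scaled reads 14 and 8. Untreated replicates 1 and 2 averaged gave 14 and 7. At an unadjusted p under 0.05 with an absolute log2 fold change of at least 1, 10 were higher and 11 lower. Thinned to 2212 reads, a median of 8 miRNAs passed (3 higher, 5 lower; range 2 to 15 over 100 draws), and all 17 and all 9 kept the sign of their median fold change. Thinning removed reads almost only from the nicorandil libraries, but the scale was also recomputed in each draw. miR-143-3p, the most abundant, went from 0.55 to a median of 0.29. The drop in calls can therefore not be put down to depth apart from scale. Leaving out 1 library gave 11 to 21 calls, 6 to 13 higher and 5 to 8 lower. The lowest total came without nicorandil replicate 2 (6 higher, 5 lower), and without untreated replicate 2 there were 13 higher and also 5 lower. No filter beyond 1 read gave 16 and 9; the filter at 10 CPM removed no further miRNA and so tests nothing. Pseudocounts of 0.1 and 10 gave 17 and 9, and 16 and 9.

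miR-148a-3p, miR-125a-5p and miR-320-3p, and miR-10a-5p and miR-122-5p among the lower ones, passed in all 17 other settings that were run on unthinned reads and with each of the 6 libraries left out. Thinning was not among those settings. Of the 26 miRNAs, 10 passed in all 6 fits without a library, 2 in 5, 3 in 4, 3 in 3, 3 in 2, 4 in 1 and 1, miR-27a-3p, in 0. For miR-125a-5p the log2 fold change ran from 0.82 to 1.33 with adjusted p-values up to 0.0191, and thinned to 2212 reads it was 0.94 with an adjusted p of 0.0503. miR-24-3p and miR-328a-3p, not past the threshold at 0.03 and -0.16, were called lower at -0.43 and -0.62 with library totals (adjusted p = 0.02 and 0.0191). The miR-125 and miR-99/100 list had a median of 0.69 (adjusted p = 0.0681) with median-of-ratios scaling and 0.46 (0.135) with library totals. The mesenchymal-enriched list had 0.55 (0.0922) and 0.33 (0.239), and in each of these settings 1 list passed in place of 3, that of liver and gut markers. With an estimated correlation 0 lists passed in camera, each of the 3 having an adjusted p of 0.208. The estimates were -0.124 for the miR-125 and miR-99/100 list, -0.000774 for the mesenchymal-enriched one and -0.151 for liver and gut markers. All lay below the preset 0.01, so a higher correlation within the lists was not the reason. Leaving out 1 library left 1 to 3 lists; the medians were 0.82 to 1.03 for the miR-125 and miR-99/100 list and 0.58 to 0.82 for the mesenchymal-enriched one, and the liver and gut list passed each time. The cause of these changes was not tested.

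The labels do not say whether libraries with the same replicate number belong together. The deviations of same-numbered libraries had correlations of 0.009, 0.044 and -0.03 across miRNAs, and not every library correlated best with its own. Most pairs of untreated libraries differed by no more than sampling noise, so these correlations cannot tell whether the replicate numbers pair the libraries. With the replicate number as a block, limma gave 17 higher and 9 lower, of which 16 and 9 were shared, miR-125a-5p stayed at 1.27, and the 3 lists passed. edgeR's quasi-likelihood test with the block gave 17 and 8.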

Other observations

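The tests in this part were chosen after the values of the miRNAs had been seen; the marker lists and the fit with library totals were fixed before the data were examined. Markers of other cell types as a set were lower after nicorandil. The 11 tested markers of blood, endothelium, liver and gut, neurons and epithelium had a median log2 fold change of -1.20, against 0.28 for the other tested miRNAs (one-sided permutation test, p = 2e-05). Some markers are neighbours, such as miR-192-5p and miR-194-5p, so neighbouring genes were also merged, which left 78 units, 9 with a marker (one-sided permutation p = 0.00025). In camera the set had an adjusted p of 6.56e-05 at the preset correlation and of 0.104, short of the threshold, at an estimated one of -0.0147, so its strength depended on the test. The filter could also tilt this set toward markers with untreated reads, since 1 read was worth more units in an untreated library. miR-129-5p and miR-223-3p had 8 reads each, but only miR-129-5p, with 4 of them untreated, was tested. Without the filter the blood cell list had a median of -0.04 over 6 members, against -0.27 over 3. The liver and gut list stayed at -1.49. The permutations were not matched on abundance. Of the 11, 6 fell and none rose (limma). miR-128-3p, a neuronal marker also abundant in these exosomes, and the blood marker miR-142-5p were above 0 at 0.34 and 0.36. The nicorandil libraries may have held a smaller share of material from other cell types, such as serum in the medium or other cells in the culture. The merged permutation test goes with this hypothesis, within these limits. How many of these miRNAs MSCs express themselves was not tested. Neighbouring miRNA genes were also compared. Of the 56 pairs of tested miRNAs whose genes lie within 50 kb of each other in GRCr8, 4 had both members past the threshold, each in the same direction: miR-125a-5p with miR-99b-5p, miR-143-3p with miR-145-5p, miR-23a-3p with miR-27a-3p and miR-192-5p with miR-194-5p. Over all 56 pairs the mean difference in log2 fold change was 0.90, against a median of 0.95 in 10000 permutations (one-sided p = 0.35), so the hypothesis that neighbours changed alike was not borne out, nor excluded.

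Of the 9 lower miRNAs, miR-10a-5p passed the threshold in 98% of the draws at equal depth, which argues against the difference in depth for this 1; the other 8 passed in 13% to 80% of the draws, too few to tell depth from a change, with a median log2 fold change over the 9 of -1.59 (95% bootstrap interval -2.41 to -1.11) before and -1.68 (-2.07 to -1.34) after thinning. The 6 lower markers of other cell types had 55, 65 and 80 reads in the untreated and 106, 103 and 71 in the nicorandil libraries. That was 1.40 times as many (95% simulated interval 1.01 to 1.94), where all miRNA reads were 6.11 times as many. A statistic for any difference in these sums among the 6 libraries was 8.39, within its simulated 95% limit of 11. It set single libraries and not the groups against each other, so it does not test the ratio of 1.40. Equal reads of a marker in both groups would put its ratio at 1. The ratio ran from 0.364 for miR-200b-3p to 1.9 for miR-192-5p, a statistic of 21.7 against a simulated 95% limit of 12.8. The same amount of foreign RNA in every library predicts equal reads only if it was read equally deeply in each. The total reads sequenced are not given, so this test cannot decide on that explanation. The heterogeneity of these ratios, 15.6 against a limit of 11.6, exceeded what 1 source of fixed composition gives. Given 1 common dispersion and 6 markers picked for being lower, this argues against 1 such source as the whole origin of these reads. Several sources in differing amounts, or foreign RNA behind part of the reads, stay open, and of the other 5 markers miR-451-5p, miR-142-5p and miR-128-3p had ratios of 3.33, 4.6 and 5.72 and miR-129-5p and miR-200a-3p of 1 and 0.4. An effect of nicorandil on what MSCs release stays open too, above all for miR-10a-5p, let-7f-5p and miR-30c-5p, which are in none of the marker lists, though let-7f-5p and miR-30c-5p kept their calls in only 4 and 3 of the 6 fits without a library.

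With library totals as the scale, 4 of the 17 higher miRNAs passed the threshold, miR-148a-3p, miR-125a-5p, miR-320-3p and miR-145-5p, which argues against the scale as the whole reason for these. For the other 13 the median log2 fold change went from 0.79 (95% bootstrap interval 0.68 to 1.02) to 0.34 (0.23 to 0.61); since they were picked for their rise, a median above 0 decides nothing, and a rise and a shift of scale cannot be told apart. At equal depth miR-148a-3p passed in 100% of the draws, which argues against the difference in depth for this 1. The other 16 passed in 0% to 52% of the draws, and their median went from 0.91 (0.68 to 1.27) to 0.63 (0.40 to 0.94), so for these 16 the difference in depth stays open. Thinning also changed the scale, so the fall of their median cannot be put down to depth alone. The median of all 17 was 0.66 at equal depth and 0.73 with median-of-ratios scaling at full depth. A response of the cells to nicorandil is the biological alternative that the design names, and it stays confounded with whatever made the nicorandil libraries deeper.

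miR-10a-5p and its close relative miR-10b-5p went opposite ways. The ratio of miR-10a-5p to miR-10b-5p reads was 0.519, 0.448 and 1.04 in the untreated and 0.0312, 0.0395 and 0.0282 in the nicorandil libraries, a 19.3-fold difference (95% conditional exact interval 10.8 to 35.9, counting error only). A fixed share of miR-10b-5p reads counted as miR-10a-5p would keep this ratio constant, so the values argue against it. Both a change in the MSCs and a loss of miR-10a-5p from another cell source stay open, the latter untested since miR-10a-5p is in none of the marker lists.

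The 26 calls (limma) can be set beside the other ways to divide the 6 libraries into 3 and 3. Of the 10 splits, 1 gave as many, the real one, and the highest of the others gave 0; 10 splits are too few for a share under 0.05. let-7c-2-3p and let-7a-1-3p had the same reads in every library, 14 in all, so they are 1 measurement under both names; neither passed the threshold.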
